A study of Mus musculus with 7 samples.

How the data were processed

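Liver RNA from 7 mice, 3 in the DIO group and 4 in the BMJ + DIO group, was fragmented, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates. The deposited table holds 1 log2 value per Ensembl gene ID and animal. Per the submitters' processing notes, the authors made these log2 values with Affymetrix Power Tools and RMA (robust multi-array average, which corrects background, normalizes probes across arrays and summarises them per gene on a log2 scale), and the notes name the GRCm38 (mm10) mouse genome. Tool versions, the array type, the probe grouping and any filter are not given in the sources used here. Probe intensities, scan dates and detection calls were not used here, so batches could not be examined and no ID could be called above background. The values ran from 0.00374 to 12.5 and had no missing entries.

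The plan, fixed before the data were examined, assumed probe sets with gene symbols. The table has 1 row for each of 33426 Ensembl IDs instead, and the reference gene table (GRCm38.p6) lists 0 Ensembl IDs, so 0 IDs were named. The rules for choosing among several probe sets of a gene therefore had no use, every ID was eligible, and the 29 gene lists and 14 cell type marker lists fixed in symbols were not tested. For the same reason the rule for single genes was limited to 4 IDs: in each direction the 2 with the smallest unadjusted p among IDs at p under 0.05, at least 1.5-fold change and no overlap between groups. The rule's exclusion of predicted genes and small RNAs could not be applied.

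Analysis used R 4.3.3 and limma 3.58.1. IDs in the lowest 40% by mean over all 7 arrays (13371 IDs, mean log2 under 2.74) were left out, and 20055 were tested. Differences are BMJ + DIO minus DIO on the log2 scale, from lmFit and eBayes with group as the sole term. Tests were two-sided, with Benjamini-Hochberg adjustment over the 20055 IDs and a threshold of 0.05. A second count used an unadjusted p under 0.05 with at least 1.5-fold change. This main fit had 5 residual degrees of freedom per ID, to which eBayes added a prior of 1.05. Array-level measures were compared by exact permutation over the 35 divisions of 7 animals into 3 and 4.

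The values carry many exact repeats: 19090 of the 33426 IDs (57.1%) hold the same value on at least 2 arrays, and 589 hold 1 value on all 7. Of the IDs tested, 305 hold 1 value throughout and 8222 hold 7 distinct values. The prior degrees of freedom were 3.83 when the 8222 IDs with 7 distinct values were fitted alone.

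The test was checked on simulated data: 19750 IDs with the real means and residual SDs and independent errors, of which 200 were changed. At the adjusted threshold of 0.05 it recovered 52% of 1.5-fold, 66% of 2-fold, 86% of 4-fold and 98% of 8-fold changes, with 11 false calls. The simulation leaves out the array-wide deviations that the real arrays share across IDs. It also takes each ID's observed residual SD as the true one, including very small SDs of IDs with repeated values. The recovered shares may therefore not hold for the real arrays.

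Replicate numbers 1 to 3 occur in both groups. Nothing in the labels ties equal numbers to a shared cage, day or litter, so the groups were compared without pairing. Alternatives planned beforehand were no filter or a 60% filter on dim IDs, quantile normalization, median centring, a trended and robust variance model, array weights, the replicate number as a block, no variance moderation, an adjusted threshold of 0.10 and leaving out each array. The default REML estimation of array weights stopped with a warning that its tolerance could not be reached. Gene-by-gene estimation was put in its place after this was seen, and both estimators were later run with a stronger prior. Cyclic loess on the tested IDs or on all IDs, equal mean and SD per array, 3 restrictions on repeated values and 2 covariates (the array's SD, and the first component of the residuals) were also added after seeing the data. So were 21 fits that combine quantile normalization, cyclic loess or equal mean and SD with leaving out 1 array. The residual component was taken from the residuals of the same group fit. By construction it removes their largest shared variation and leaves the group difference as it is. The p-values with it can therefore be too small, and its calls are not ordinary calls. The alternatives on several probe sets per gene, on unnamed probe sets and on gene set tests were not run, since the table gives no such entries or names.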

Results

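Liver RNA from 7 male C57BL/6J mice was profiled on expression arrays to ask how bitter melon juice changes liver gene expression in diet-induced obesity. C57BL/6J is an inbred strain that gains weight readily on fatty food. All mice received a diet with 60% of its energy from fat from 4 to 16 weeks of age, and stayed on it for a further 40 days. During those 40 days, 4 mice were also gavaged daily with freeze-dried bitter melon juice (BMJ, from the fruit of Momordica charantia) at 200 mg per kg body weight (the BMJ + DIO group). The other 3 received the diet only (the DIO group). No lean group and no untreated time point were analysed here, so every value compares obese mice with and without the gavaged juice. No gavage is described here for the DIO group, so the juice cannot be told apart from daily gavage and handling. Below, an effect or difference with the juice means both together. The labels give all mice an age of 16 weeks, although the feeding protocol runs 40 days past that age. Each array held 1 log2 value for each of 33426 Ensembl gene IDs, and 20055 IDs entered the tests after the dimmest 40% were left out. The number of arrays, 3 and 4, limits the precision of each comparison.

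The values carry Ensembl gene IDs alone, and the reference table used here pairs 0 of the 33426 IDs with a gene symbol. The changes are therefore described for groups of IDs and for 4 single IDs, without gene names, gene functions or genomic positions. The pathway and cell type lists fixed beforehand are written in gene symbols and could not be tested, so it was not determined whether lipid, glucose, bile acid, inflammatory or other gene groups differed between the mice.

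The first question was how far the livers resembled each other before any gene was tested. The 4 BMJ + DIO livers were alike, with pairwise Pearson correlations of 0.9755 to 0.9814 across the tested IDs (genes are not independent replicates). The 3 DIO livers were less alike, at 0.9114 to 0.9667. DIO replicate 3 stood apart from all the others. Its mean correlation with the other 6 arrays was 0.924, while the other arrays lay between 0.964 and 0.969. The first principal component held 58.2% of the variance, with scores of 68.0 for DIO replicate 3, 18.9 for DIO replicate 2 and -24.8 for DIO replicate 1. The BMJ + DIO livers scored between -26.2 and -1.79 on it, next to DIO replicate 1. The mean score was 20.7 ± 46.4 (SD, n = 3) in DIO and -15.5 ± 11.6 (SD, n = 4) in BMJ + DIO, a difference within the spread of the DIO animals (exact permutation test over 35 splits, two-sided p = 0.143, adjusted p = 0.429 over 3 array measures, smallest p possible 0.029).

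Highly expressed IDs read lower in part of the DIO group. Among the 1489 IDs with a mean log2 value of 7 or more, the mean deviation from the 7-array median was -0.586 in DIO replicate 3 and -0.166 in DIO replicate 2. In DIO replicate 1 it was 0.135, higher than any BMJ + DIO array. As a result 85.0% of these IDs had a higher mean in BMJ + DIO, with a median difference of 0.222 on the log2 scale, which became 0.031 without DIO replicate 3 and -0.010 after cyclic loess normalization. IDs between 5 and 7 showed the same shift in smaller size, with a median of 0.165 that became 0.022 without DIO replicate 3. Dimmer IDs ran the other way: the median difference was -0.015 between 3 and 5, and -0.046 under 3, where 36.3% of 1629 IDs were higher in BMJ + DIO. Without DIO replicate 3 these medians became -0.009 and -0.011, and after cyclic loess -0.008 and 0.011. Cyclic loess evens out differences that follow brightness, so the small medians after it come by construction. They do not tell a technical shift from a real one. The SD of the log2 values of an array measures how wide its signal range is. It was 1.86 ± 0.106 (SD, n = 3) in DIO and 1.92 ± 0.0298 (SD, n = 4) in BMJ + DIO (exact permutation test, two-sided p = 0.286, adjusted p = 0.429). The mean log2 value per array was 3.47 ± 0.0365 in DIO and 3.49 ± 0.00487 in BMJ + DIO (exact permutation test, two-sided p = 0.543, adjusted p = 0.543).

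**Figure D1:**
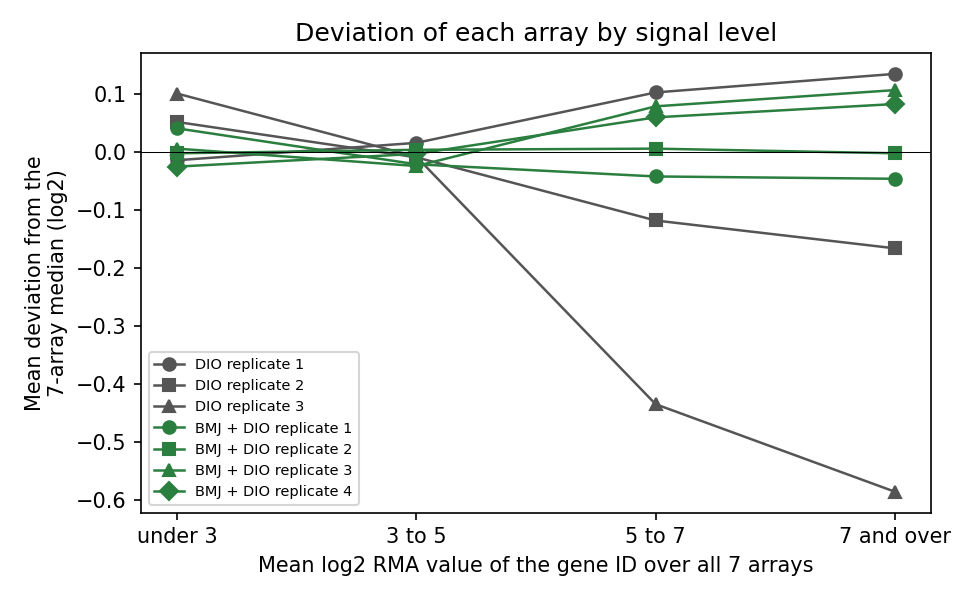
Mean deviation of each array from the 7-array median (vertical axis, log2) for gene IDs grouped by their mean log2 RMA value (horizontal axis), with DIO arrays in grey and BMJ + DIO arrays in green. DIO replicate 3 falls to -0.586 among the brightest IDs, while the 4 BMJ + DIO arrays stay between -0.046 and 0.107 there.

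The second question was which gene IDs differed between the groups. In the moderated test of limma, 0 of 20055 IDs passed a Benjamini-Hochberg adjusted p of 0.05, in either direction, and the smallest adjusted p was 0.571. In the same test the smallest adjusted p came close to the threshold without DIO replicate 1 (0.0504) and after cyclic loess on the tested IDs (0.0533). Without any 1 of the other arrays it lay between 0.429 and 0.763. At an unadjusted p under 0.05 there were 1285 IDs, 728 with a higher and 557 with a lower mean in BMJ + DIO. The 34 other divisions of the same mice into 3 and 4 gave 214 to 4305 such IDs, with a median of 367.5, and 3 of them gave as many or more. This count ran from 550 without DIO replicate 2 to 5823 without DIO replicate 1. Of the 1285, 343 also differed at least 1.5-fold: 207 were higher and 136 lower with the juice. At least a 2-fold difference was present in 80 IDs, and at least a 4-fold difference in 3. Over the 343 IDs the fitted differences ran from -1.83 to 2.21 on the log2 scale. The count of 343 ran from 186 without DIO replicate 3 to 2091 without DIO replicate 1. All 4 treated livers lay on one side of all 3 control livers for 705 of the 20055 IDs, or 3.52%. The mean over all 35 divisions of the mice was 3.02%, and 7 of the 34 others separated as many IDs or more. Of the 343 IDs, 200 had such separate groups, 109 higher and 91 lower in BMJ + DIO.

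The excess of higher over lower IDs among the 343 depended on single arrays. The share of higher IDs was 60.3% on the deposited values and 50.4% of the 343 IDs found after cyclic loess. That method takes out a shift shared by IDs of like brightness, whether technical or real. On the deposited values the share was 78.2% without DIO replicate 1 and 58.7% without BMJ + DIO replicate 1. It lay between 49.5% and 51.8% without any 1 of the other 5 arrays. Fits with array weights, which estimate how reliable each array is from its distance to its group's mean, depended on the estimator. The default estimation stopped before convergence, gave DIO replicate 2 a weight of 775 and called 8327 IDs past the adjusted p of 0.05. Gene-by-gene estimation, taken up after that failure was seen, weighted the same array 5.51 against 0.261 and 0.109 for the other control arrays and called 3705 IDs, 2332 higher and 1373 lower. With a stronger prior on equal weights, both estimators called 0 IDs, with a smallest adjusted p of 0.0601 for REML, close to the threshold, and 0.181 gene by gene.

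The IDs with the clearest separation on each side are given with their values. They were the 2 with the smallest p per direction among those with at least 1.5-fold change and no overlap, so their estimated differences tend to be too large. None passed the adjusted threshold (limma, adjusted p = 0.571 for each). ENSMUSG00000037847 averaged 5.46 ± 0.31 (SD, n = 3) in DIO and 6.76 ± 0.09 (SD, n = 4) in BMJ + DIO, 2.46-fold higher with the juice, a log2 difference of 1.30 with a standard error of 0.15 and a 95% interval of 0.94 to 1.66. ENSMUSG00000102095 averaged 8.79 ± 0.11 in DIO and 9.61 ± 0.13 in BMJ + DIO, 1.76-fold higher (log2 difference 0.82, standard error 0.09, interval 0.60 to 1.04). ENSMUSG00000020889 averaged 8.25 ± 0.22 in DIO, where it was among the brighter IDs, and 6.55 ± 0.39 in BMJ + DIO. That is 3.26-fold lower with the juice (log2 difference -1.70, standard error 0.23, interval -2.27 to -1.14). ENSMUSG00000020163 averaged 5.43 ± 0.24 in DIO and 4.37 ± 0.18 in BMJ + DIO, 2.09-fold lower (log2 difference -1.06, standard error 0.15, interval -1.42 to -0.71). The groups did not overlap for any of these 4 IDs, which the choice of IDs required.

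**Figure D2:**
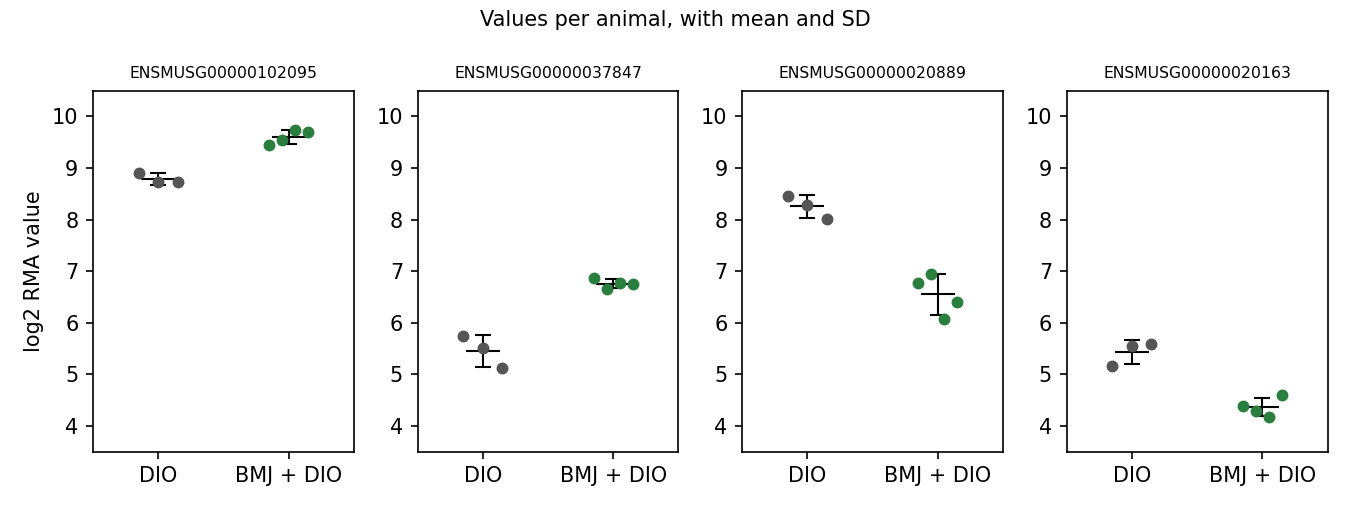
log2 RMA values (vertical axis) of the 4 gene IDs in each animal, with DIO in grey (n = 3) and BMJ + DIO in green (n = 4); horizontal marks are means and error bars are SD. The groups do not overlap for any of the 4 IDs; ENSMUSG00000020889 spans 8.02 to 8.45 in DIO and 6.07 to 6.94 in BMJ + DIO.

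Because the animals within the DIO group differed, the same counts were set against all other ways of dividing the 7 mice into 3 and 4. The study's own division gave 343 IDs at an unadjusted p under 0.05 and at least 1.5-fold. Of the 35 divisions, 4 gave at least as many, the study's own included, and the largest count, 1174, came from setting DIO replicate 2, DIO replicate 3 and BMJ + DIO replicate 1 against the rest. In limma's test no division of the 35 gave an ID past the adjusted threshold.

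**Figure D3:**
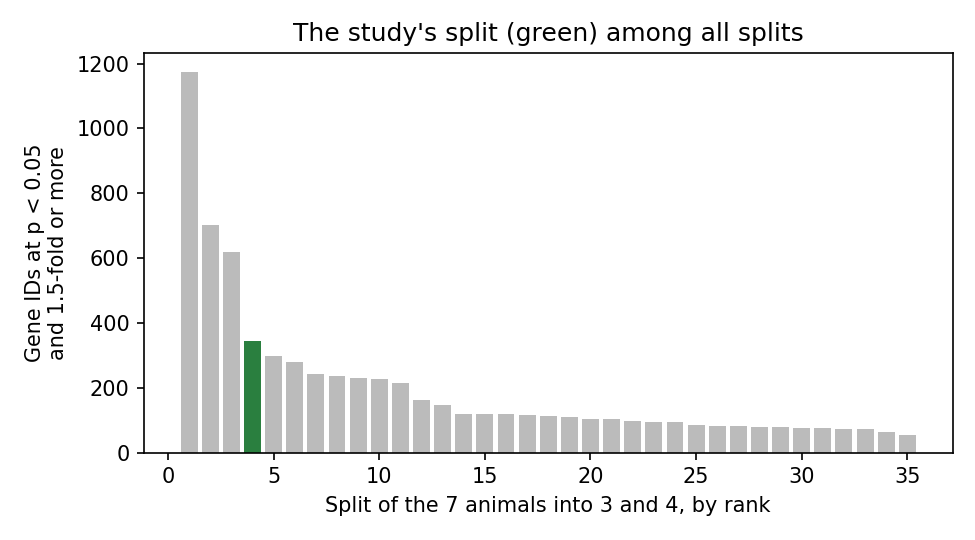
Number of gene IDs at an unadjusted p under 0.05 and at least 1.5-fold (vertical axis) for each of the 35 divisions of the 7 animals into 3 and 4, ranked by that number (horizontal axis). The study's division, in green, gives 343 IDs; the highest bar is 1174.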

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

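The weights other than the default, cyclic loess, equal SD, repeated value and covariate fits were chosen after seeing the data. Of 27 alternatives, 23 left 0 IDs past the adjusted p of 0.05. The exceptions were default array weights, not converged (8327 IDs), gene-by-gene weights (3705), cyclic loess over all IDs (1) and the residual component (2800). With that component p can be too small. Both weight estimators gave 0 with a stronger prior, which by construction draws the weights together. Of 21 fits joining a normalization with leaving out 1 array, 1 made calls (26 IDs, equal mean and SD without DIO replicate 1). The 343 IDs at an unadjusted p under 0.05 and 1.5-fold became 527 with no dim filter (more IDs tested), 202 without variance moderation, 174 with the replicate block, 204 with the array SD and 725 with the residual component as a covariate. The block also takes BMJ + DIO replicate 4, which has no same-numbered control, out of the difference. Leaving out that array alone gave 221. Array weights gave 1547 by default, 1267 gene by gene, and 728 and 1064 with a stronger prior for gene-by-gene and REML estimation. Leaving out 1 array gave 186 (without DIO replicate 3) to 2091 (without DIO replicate 1); 12 of 26 alternatives stayed within 1.5 times. Apart from the filter and the prior, the cause was not tested. The share of higher IDs, 60.3%, ran from 45.1% (array SD) to 78.2% (without DIO replicate 1), with 72.3% for the residual component and 70.9% with the lowest 60% left out. The 1285 IDs at an unadjusted p under 0.05 became 449 with the replicate block, 550 to 5823 without 1 array and 9656 with default weights. Same-numbered animals did not deviate together (correlations -0.36, -0.09 and -0.30). Deviations that an array shares across IDs enter these 3 values, so they cannot show whether equal numbers pair animals. With the block 0 IDs passed. The 4 single IDs kept their direction in all 26 alternatives, but many of these could not have changed it. Having been chosen for groups without overlap, the IDs could not turn when 1 array was left out, with array weights or with the block. The filters, variance models, repeated value restrictions and residual component leave the difference as it is. Only the normalizations, the centring and the array SD could have turned it. All 4 IDs passed the adjusted p of 0.05 with default weights, gene-by-gene weights or the residual component (same limit). ENSMUSG00000037847 also did after cyclic loess over all IDs. The highest adjusted p was 0.856. Gene set and probe set alternatives were not run, and signal over background was not examined here.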

Other observations

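The tests below were chosen after the results they measure were seen, apart from 3 that were set up before: the divisions for the set of 67 IDs, the divisions with gene-by-gene weights, and the common set of levels. A set of 67 IDs passed an unadjusted p under 0.05 and 1.5-fold in one direction on the deposited values, after cyclic loess and in each of the 7 fits without 1 animal. Of these, 38 were higher in BMJ + DIO, by 0.76 to 2.21 on the log2 scale, and 29 were lower, with differences of -1.70 to -0.65. The 4 single IDs of the report are among them. Other divisions of the mice gave sets as large: 5 of the 35, the real one included, with 276 IDs in the largest, so chance could not be excluded for the size of this set. The time of day and the feeding state at collection are not given in the sources used here, so a difference between the groups in either stays open for every ID, untested. An effect of the gavage itself stays open in the same way.

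Whether any juice effect stands out from chance differed between the tests. For the 343 IDs at an unadjusted p under 0.05 and 1.5-fold, 4 of the 35 divisions gave as many, with 1174 the highest of the others. With the residual component as a covariate, 4 of 35 divisions reached the real 2800, and the highest other gave 5467. The 1285 IDs at an unadjusted p under 0.05 were matched by 4 of 35 divisions (highest other 4305), and the 705 IDs without overlap by 8 of 35 (highest other 3820). Chance could not be excluded for any of these counts. For IDs past the adjusted threshold the real count was 0, so all 35 divisions give as many by construction and this says nothing about chance (0 is also the highest of the others). The largest counts came from a division with DIO replicates 2 and 3 and 1 treated liver on one side, which shows a structure among the 7 samples. That division shares 2 of its 3 livers with the real one, and no test separated this structure from an effect of the juice.

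With gene-by-gene array weights, 1 of 35 divisions, the real one, reached 3705, and the highest other gave 2244. A rank of 1 of 35 is the strongest result the divisions can give. It was not adjusted over the other counts set against the same divisions, so it is weak evidence against chance for that fit. The gene-by-gene fit is 1 of 4 versions of the weights, adopted after the default had failed. With a stronger prior the real count was 0 and the highest other 1, and as all 35 divisions then give as many by construction, this has no bearing on chance. The count of 3705 may come from 1 array carrying most of its group's weight: the 2 divisions with the most calls are those with the largest single weights, by a margin of 0.27 over all other divisions. DIO replicate 2 lay near the DIO mean on the first principal component (18.9 against 20.7). DIO replicates 1 and 3 lay on either side of it, at -24.8 and 68.0, so a high weight can reflect that position and not reliability. An effect of the juice that shows once DIO replicates 1 and 3 are given little weight stays open, and these weights cannot decide it.

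DIO replicate 3 stood apart from the other 6 arrays. After cyclic loess had removed the trend with brightness, its mean correlation with the other arrays was 0.939, against 0.924 before. That was still 0.0267 below the lowest of the other 6, whose SD was 0.00197, so the trend alone does not account for all of it. Whether a compressed signal range does was not decided. A correlation is unchanged when an array is compressed linearly, and noise in a compressed array would remain after loess. An exchange with a treated animal cannot be told apart from a true control: its correlation with the treated arrays minus that with the other control arrays was -0.0126, within the SD of 0.018 of its 6 correlations. No treated array lay nearer the other 2 controls than the other treated arrays, as an exchange would need, but the differences were 0.0017 to 0.00656, for 3 of the 4 within the SD of their correlations, and DIO replicate 1 also resembles the treated arrays. Partial RNA degradation, another piece of the liver and a real difference between obese mice may each contribute and stay open. They were not tested: no gene names were at hand, and probe intensities were not used here. Gene names alone might not settle them.

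Many IDs hold the same value on several arrays. A floor for dim IDs does not explain them all, since 29.6% of the 730 IDs with a mean log2 value of 8 or more hold one. If values were taken from 1 common set of normalized levels, they should also recur at other IDs. Among the bright IDs 2.94% of values recurred at another ID on another array, 2.38 times the 1.23% found after shifting each value at random by up to 0.01. A common set may thus contribute, but the test does not measure what share of the repeats it would produce. Their cause was not settled.

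The treated livers varied less than the control livers. The log2 of the ratio of the variance in DIO to that in BMJ + DIO had a median of 2.03, over the IDs with a variance above 0 in both groups. A hypothesis is that the juice made the livers more alike. In 3 of the 35 divisions this median was as high, with 2.09 the highest of the others, so chance could not be excluded. In every division the group that held DIO replicate 3 was the more variable. The median was 1.27 to 2.09 where that array was in the group of 3, and -2.26 to -1.08 elsewhere. It therefore cannot tell an effect of the juice from the deviation of 1 array. The correlation of DIO replicates 1 and 2, 0.9667, lay below the 6 correlations among treated livers, but 2 arrays give no test.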
